A study of Homo sapiens with 14 samples.

How the data were processed

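RNA sequencing was run on 3 human ovarian cancer cell lines, OVCAR-3, CAOV3 and SKOV3, grown with GSK-J4 or GSK-J5 at 2.5 µM. GSK-J4 is a cell-permeable inhibitor of the histone H3 lysine 27 demethylases KDM6A (UTX) and KDM6B (JMJD3), and GSK-J5 is the isomer used as its inactive control. The 14 samples in the labels hold 22 libraries, because each sample of the first set covers replicates 1 and 2 of a group. At 72 h every line had 3 libraries per compound, and OVCAR-3 also had 2 per compound at 48 h. Replicate 3 was a later library set: the labels name another RNA kit, other medium text and poly(A) selection for it. The set and replicate 3 are therefore one and the same, with both compounds in each set. No library without a compound is in the labels, so every effect is GSK-J4 relative to GSK-J5. One OVCAR-3 column header gives the time and replicate in shortened form and was read as the third GSK-J4 library of 72 h, the only sample left for it. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries.

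The deposited values are raw counts, 1 count per read or fragment assigned to a gene, as whole numbers without normalization, for 58825 versioned Ensembl gene identifiers in each of 3 tables. The submitters' processing notes name STAR, DESeq2 and the genome build GRCh38 (hg38), without a version or role. The counting tool, its strand setting and the annotation release are not given in the sources used here, so counts of antisense genes and of near-identical paralogs are uncertain. Symbols came from a gene name table for 58472 identifiers and from GENCODE release 29 for 345, and 8 stayed without a name. Coordinates are on GRCh38 from GENCODE release 29, which held 58552 of the identifiers.

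Total counts per library ran from 24037007 to 37990707. Over a library, the floor of 3 counts that a count of 0 allows was between 0.079 and 0.12 CPM, the counts scaled to a common library total. Intervals and floors from counts cover counting error only. Where a group held no count of a gene, the fold is given as a bound against 3 counts over the group, and where it held 1 to 3 counts as a ratio with its 95% counting interval.

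All fits were run in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and quasi-likelihood models were fitted with glmQLFit (robust) and tested with glmQLFTest. The library set was a covariate. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Each line at 72 h had its own fit of 6 libraries. The 48 h effect in OVCAR-3 and the difference between 72 h and 48 h came from 1 fit of all 10 OVCAR-3 libraries, because 48 h had 2 replicates per compound. Differences between lines came from 1 fit of the 18 libraries of 72 h with the set nested in the line. Fold changes are edgeR log2 estimates with a prior count of 0.125, given with a standard error (SE) and 95% interval. The SE was worked back as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. The interval was built from that SE and the t distribution, so both are approximate, above all for very large changes. Levels are TMM-scaled CPM, as mean with standard deviation (SD). The numbers 1 to 3 might pair the libraries across compounds, so the deviations from the group means were correlated: in SKOV3 all 3 same-numbered pairs correlated above 0.1 (0.443, 0.446 and 0.779), which follows the library set, and the value with the replicate number as a block is given beside that result. In OVCAR-3 and CAOV3 at least 1 pair was below 0.1.

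Before the data were examined, 32 gene lists, the tests, the alternatives and the rule for named genes were fixed. Of 682 list members, 680 were matched. Lists were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The alternatives were camera with an estimated correlation and fry. Named genes were KDM6A and KDM6B always, the 6 highest and 6 lowest log2 fold changes among called genes with a mean log2 CPM of at least 1, the same direction in every same-numbered pair and a symbol without a period, and the 2 called members with the largest change from each list that passed. For differences between times or lines the 4 highest and 4 lowest called genes were taken, and for the common response the 10 with the largest value of the smallest change over the lines, in each direction. Genes named outside this rule are said to have been chosen after their values were seen.

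Alternatives covered DESeq2 1.42.0 size factors and its Wald test, limma voom, no low-count filter, no set term, the replicate block, other sets of libraries in a fit, a fold threshold, and leaving out each replicate and each library. After the data had been seen, the named-gene rule and the list tests were repeated on replicates 1 and 2 alone, and corrections of each library for GC content and gene length (natural splines with 5 degrees of freedom) were added. The fits were tested on simulated data in which 200 genes were changed, by a log2 value of 1 or 2. Of those changed by 2, edgeR recovered 79% in OVCAR-3 at 72 h and 100% in CAOV3 and SKOV3. It recovered 90% in OVCAR-3 at 48 h and 48% for the difference between times. The simulation gave every gene the same dispersion (spread between libraries) and every replicate the same change. In the real OVCAR-3 libraries of 72 h the change was smaller in replicate 3, so these shares are not the recovery in the real data. Groupings of the libraries other than the real one were also fitted, with all 10 splits within a line and 21 draws for the 3-line fit. The results of a few genes that the rule takes are not reported here.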

Results

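RNA was sequenced from 3 human cell lines derived from ovarian cancers, OVCAR-3, CAOV3 and SKOV3, after 72 h in 2.5 µM GSK-J4 or 2.5 µM GSK-J5. Each line had 3 libraries per compound at 72 h, and OVCAR-3 also had 2 libraries per compound at 48 h. Replicates 1 and 2 belonged to a first library set and replicate 3 to a second, in every line. The comparisons ask which genes change when the H3K27 demethylases are inhibited, whether the change differs between 48 h and 72 h, and whether it differs between the lines. Total counts ran from 24037007 to 37990707 per library, and between 16802 and 20252 genes were tested in the fits with all replicates. Fold changes are given on the log2 scale with their SE, GSK-J4 relative to GSK-J5.

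In OVCAR-3 at 48 h (n = 2 libraries per compound), the genes that rose with GSK-J4 included GDF15, NGFR, TRIB3 and MT2A, and those that fell included FAM111B and RRM2. GDF15, a secreted stress cytokine, rose 281-fold over GSK-J5 (log2 8.14, SE 1.54, adjusted p = 0.0214), from 0.967 ± 0.2 to 272 ± 20.6 CPM (SD, n = 2). TRIB3, a pseudokinase induced by ATF4, rose 35.5-fold, and MT2A, a metallothionein that binds zinc and copper, rose 36.6-fold. RRM2, a subunit of ribonucleotide reductase, was 14.4-fold lower, from 316 ± 12.1 to 21.9 ± 0.198 CPM. Of 17402 genes tested with edgeR, 1969 rose and 1327 fell, 18.9% of the total. With DESeq2 size factors in place of TMM, 1747 rose and 1541 fell, so the balance depends on the scaling. The GSK-J4 libraries of 48 h had 15606 and 15406 genes with at least 10 counts, against 16425 and 16576 with GSK-J5. Mitochondrial ribosomal RNA held 0.415% and 0.275% of the counts with GSK-J4, against 0.0736% and 0.0694% with GSK-J5. NGFR, the p75 neurotrophin receptor, rose 69.8-fold (log2 6.13, SE 0.428, adjusted p = 0.0043). LAMP3 (log2 5.59), a lysosomal membrane protein, and DMGDH (5.57), a mitochondrial enzyme of choline breakdown, also rose. Among called genes with a mean log2 CPM of at least 1, as the naming rule asks, the lowest changes were those of FAM111B (log2 -4.80), BLACAT1 (-4.21), TTC30A (-4.19), the histone gene H2BC8 (-4.09), C14orf132 (-4.06) and RRM2 (-3.85). Among the targets of the compound, KDM6B rose 1.85-fold (log2 0.89, SE 0.158, adjusted p = 0.0188), from 93.7 ± 10.1 to 173 ± 24.7 CPM, while KDM6A had a log2 change of 0.33 with an interval from -0.05 to 0.70 (adjusted p = 0.161).

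Of the 32 gene lists, 8 were higher and 8 lower at 48 h by camera with the preset correlation, and 0 of these 16 passed with an estimated one. The 8 higher lists had an adjusted p = 0.409 with an estimated correlation, except for 0.457 in the NRF2 list and 0.465 in the synthetases. Of 35 measured members of the ATF4 and amino acid response list, 19 rose, 0 fell and 16 did not pass (26 and 0 adjusted over the list alone), with a median log2 change of 1.73 (adjusted p = 1.3e-08). Among 20 aminoacyl-tRNA synthetases 8 rose, led by AARS1 (2.24) and SARS1 (2.16), and 15 rose and 1 fell adjusted over the list alone (adjusted p = 0.000102). Endoplasmic reticulum chaperone and unfolded protein response genes rose in 8 of 22 cases (9 adjusted over the list alone, camera adjusted p = 0.00908), among them ERN1 (3.46), the sensor kinase IRE1, and HERPUD1 (1.90). Metallothionein and zinc export genes rose in 5 of 7 cases over all genes and adjusted over the list alone, with a median of 5.19 (adjusted p = 0.00121). MT1X rose by a log2 value of 5.79, and MT1M had 359 counts against 1, a ratio of 404 with a counting interval from 72.1 to 16000; reads can be shared among these paralogs, so the split between them is uncertain. NF-kB and inflammatory cytokine genes rose in 8 of 18 cases (10 higher and 1 lower adjusted over the list alone, adjusted p = 8.3e-05), with the chemokine gene CXCL3 (3.60) and IL6 (3.20). Autophagy and lysosome genes rose in 7 of 20 cases (11 adjusted over the list alone, adjusted p = 0.000421), among them the lysosomal transcription factor TFEB (2.47) and WIPI1 (1.47). The NRF2 target list passed with 3 genes higher and 1 lower of 18 (4 and 1 adjusted over the list alone, adjusted p = 0.00554). Its member OSGIN1 rose (3.13), and AKR1B10 went from 33 counts to 0, at least 9.77-fold lower. Of 25 p53 targets 9 rose and 1 fell (10 and 2 adjusted over the list alone, adjusted p = 0.0446), among them GADD45A (4.19), a growth arrest gene.

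The 8 lower lists at 48 h had an adjusted p = 0.409 with an estimated correlation, except for 0.457 in the HOX and homologous recombination lists and 0.534 in cholesterol synthesis. Among them, 24 of 30 mitosis and G2/M genes fell and 0 rose (26 adjusted over the list alone, median -1.07, adjusted p = 1.2e-11). MKI67, the proliferation marker, fell by 2.11 on the log2 scale and ASPM, a spindle pole protein, had a change of -2.57. DNA replication and G1/S genes fell in 19 of 30 cases (25 adjusted over the list alone, median -1.39, adjusted p = 3e-10), among them RRM2 and UHRF1 (-3.15). In the homologous recombination and Fanconi anaemia list 14 genes fell and 2 rose of 32 (18 and 3 adjusted over the list alone, adjusted p = 0.00154), with XRCC2 (-2.91) and FANCL (-2.34). Replication-dependent histone genes fell in 9 of 22 cases and 1 rose (13 and 1 adjusted over the list alone, adjusted p = 0.000208), with H2AC11 at -3.35; the sequences of these genes are close to each other. Heat shock genes fell in 6 of 13 cases (6 lower and 1 higher adjusted over the list alone, adjusted p = 0.00703), led by the near-identical HSP70 genes HSPA1A (-1.89) and HSPA1B (-1.75). HOX genes had 5 lower and 1 higher of 28 (6 and 2 adjusted over the list alone, median -1.27, adjusted p = 0.0175), with HOXA4 at -2.41 and HOXB9 at 3.12. In the ovarian and Mullerian lineage list WT1 fell (-2.08) and KLK6 rose (0.78) among 15 members (7 lower and 1 higher adjusted over the list alone, adjusted p = 0.0113). Cholesterol synthesis genes fell in 3 of 23 cases, among them ACAT2 (-1.15) and SQLE (-0.74), and in 0 adjusted over the list alone (adjusted p = 0.0257). By fry 18 lists passed.

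The 48 h count rests on every library of that time: without any single 48 h library edgeR called 0 genes, and without replicate 3 of 72 h in the shared fit it called 4978 higher and 5098 lower of 17090.

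**Figure D1:**
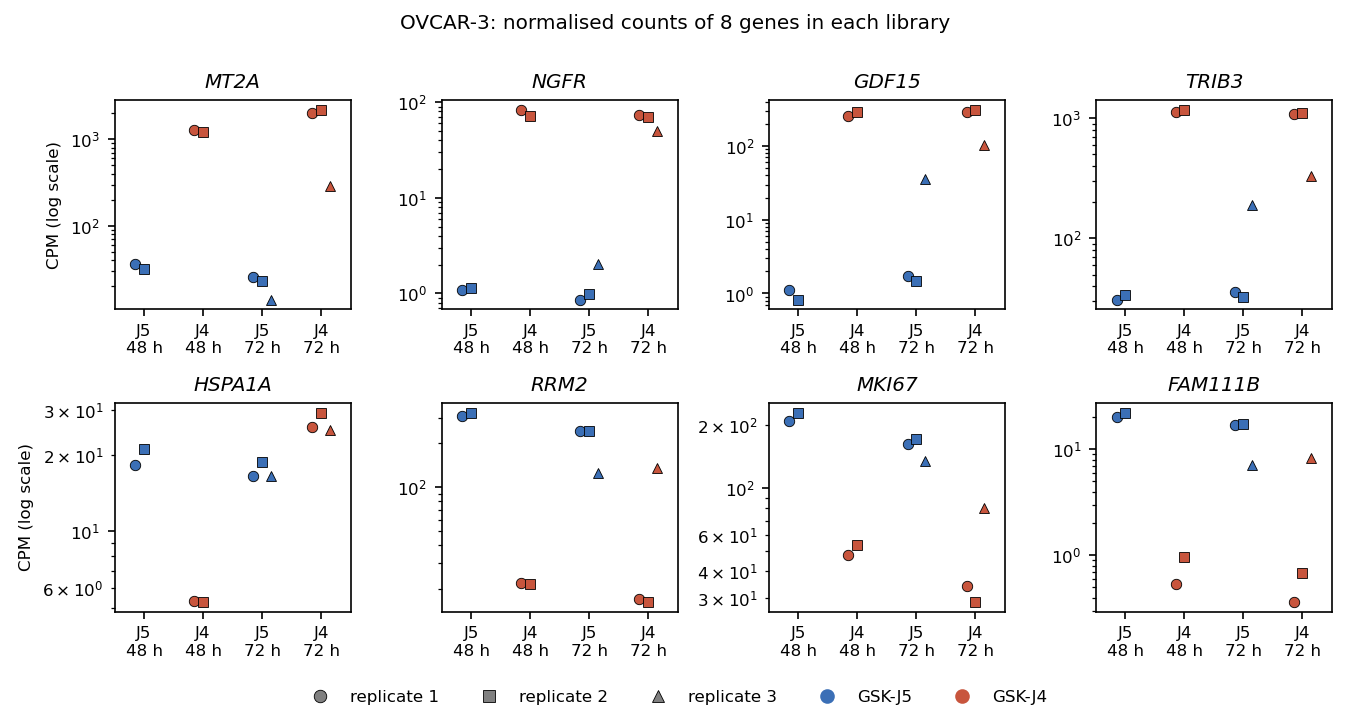
Levels of MT2A, NGFR, GDF15, TRIB3, HSPA1A, RRM2, MKI67 and FAM111B in each OVCAR-3 library, as CPM on a log axis, by compound and time, with points for single libraries. MT2A was at 1238 CPM on average with GSK-J4 at 48 h against 33.9 CPM with GSK-J5, and at 72 h GSK-J4 replicate 3 (290 CPM) lay below replicates 1 and 2 (2004 and 2185 CPM).

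In OVCAR-3 at 72 h (n = 3 libraries per compound), NGFR, EDN2, STAC and the metallothionein gene MT1M rose with GSK-J4, and the change in many genes was smaller in replicate 3 than in the other two. NGFR (ENSG00000064300.9, chromosome 17, 49495293 to 49515017 on GRCh38) rose 52.7-fold, from 1.28 ± 0.639 to 65.1 ± 12.8 CPM (SD, n = 3; log2 5.72, SE 0.419, adjusted p = 0.0379). EDN2, which encodes the vasoconstrictor peptide endothelin 2 (ENSG00000127129.10, chromosome 1, 41478775 to 41484673), rose 23.3-fold, from 2.84 ± 1.75 to 78.4 ± 58.6 CPM (log2 4.54, SE 0.298, adjusted p = 0.0316). STAC (ENSG00000144681.10, chromosome 3, 36380344 to 36548007) rose by 3.81 (SE 0.257, adjusted p = 0.0316). MT1M (ENSG00000205364.4, chromosome 16, 56632233 to 56633986) had 1326 counts against 1, a ratio of 1620 with a counting interval from 291 to 64200 (adjusted p = 0.0259). CACNG1, a calcium channel subunit, rose too (log2 6.26, SE 0.443, adjusted p = 0.0316); it lay below the expression minimum and was named after its values were seen. These 5 were all the genes called of 16802, with 0 lower, and 7244 genes had an unadjusted p below 0.05 in edgeR. The DESeq2 Wald test called 6334 genes, and the fit of all 10 OVCAR-3 libraries called 3983 higher and 3635 lower. KDM6A had a log2 change of -0.01 (interval -0.42 to 0.40, adjusted p = 0.971) and KDM6B one of 0.16 (interval -0.19 to 0.51, adjusted p = 0.40).

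By camera, 7 lists were higher and 5 lower at 72 h in OVCAR-3, where 0 members passed over all genes except MT1M. With an estimated correlation 0 of the 12 lists passed (adjusted p = 0.614 with an estimated correlation, and 0.630 for homologous recombination and histones). Adjusted over the list alone, 16 of 20 aminoacyl-tRNA synthetases rose and 0 fell (median log2 0.89, adjusted p = 9.5e-06), as did 14 of 16 NRF2 targets with 1 lower (1.2, adjusted p = 6.3e-06). NF-kB and cytokine genes had 11 higher and 1 lower of 18 adjusted over the list alone (1.83, adjusted p = 7.3e-06). Autophagy and lysosome genes had 10 and 1 of 20 (0.60, adjusted p = 9.3e-05), and endoplasmic reticulum chaperones 8 and 0 of 22 (0.51, adjusted p = 0.00128). Metallothioneins had 5 higher and 1 lower of 7 adjusted over the list alone (3.97, adjusted p = 0.0022) and heat shock genes 5 and 0 of 13 (0.41, adjusted p = 0.0220). The lower lists were mitosis with 20 of 30 lower and 1 higher adjusted over the list alone (-0.64, adjusted p = 5.3e-06) and DNA replication with 21 of 30 lower and 0 higher (-1.05, adjusted p = 1.2e-05). Homologous recombination had 8 of 32 lower and 2 higher (-0.95, adjusted p = 0.0218). Replication-dependent histones (21 measured, -0.95, adjusted p = 0.0134) and HOX genes (27 measured, -1.03, adjusted p = 0.0432) had 0 members past the threshold adjusted over the list alone. The ATF4 list was not called, with a median of 0.47 over 34 genes (adjusted p = 0.122) and 5 higher and 4 lower adjusted over the list alone.

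The few calls at 72 h went with the spread between replicate 3 and the others. GSK-J4 replicate 3 had 290 CPM of MT2A against 2004 and 2185 in replicates 1 and 2, and GSK-J5 replicate 3 had 191 CPM of TRIB3 against 35.9 and 32.4. On replicates 1 and 2 alone, a choice made after the values were seen, edgeR called 5626 genes higher and 6047 lower of 16281, or 71.7% of the total. TMM scaling takes most genes as unchanged, so with this share called the balance of higher and lower genes rests on the scaling. GSK-J4 replicates 1 and 2 had 14714 and 14680 genes with at least 10 counts, and their 20 highest genes held 12.7% and 13% of the counts, against 16444 and 16504 genes and 8.12% and 7.74% with GSK-J5. In replicate 3 these values were 16231 genes and 9.81% with GSK-J4 and 16492 genes and 8.65% with GSK-J5. In the fit of all 6 libraries, leaving out any single library of replicates 1 or 2 left 0 calls. Without GSK-J5 replicate 3 that fit called 11820 genes, and without GSK-J4 replicate 3 it called 11823. Without replicate 1 it called 25, and without replicate 2 it called 9.

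In these replicates 1 and 2 at 72 h (n = 2 per compound), GDF15 rose 190-fold (log2 7.57, SE 0.149) and MT2A 88.2-fold (6.46, SE 0.134). HSPA6, a heat shock protein kept low in unstressed cells, rose by a log2 value of 6.89, MT1X by 6.51, NGFR by 6.33, DMGDH by 6.20 and ATF3, a stress-induced transcription factor, by 6.11. Among the genes that met the naming rule the lowest changes were in PCK1 (-6.23), the gluconeogenic enzyme, LRRTM1 (-5.70), TMEM100 (-5.35), TTC30A (-5.32), LRRC32 (-5.03) and FAM111B (-4.97). Of the lists, 12 passed by camera. With an estimated correlation 0 lists passed (adjusted p = 0.346 with an estimated correlation for most, 0.360 for NF-kB and 0.456 for histones). The ATF4 list had 24 genes higher and 6 lower of 34 (median 1.10, adjusted p = 2e-05), and the synthetases 19 higher and 0 lower, with SARS1 (2.63) and YARS1 (2.44). NRF2 targets had 15 higher and 1 lower, with OSGIN1 (3.81) and GCLC (3.27), the catalytic subunit of glutathione synthesis. NF-kB and cytokine genes had 16 higher and 1 lower, with CXCL3 at 4.75 and IL6 at 71 counts against 3, a ratio of 37.9 (interval 12.5 to 188). DNA replication genes had 26 lower and 2 higher, with UHRF1 (-4.50), and mitosis genes 23 lower and 2 higher, with ASPM (-2.98) and MKI67 (-2.39). In the homologous recombination list 23 fell and 6 rose, with XRCC2 at -3.25, and among histones 14 fell and 1 rose, with H3C8 at -4.25 and H2AC11 at -3.97. HOX genes had 16 lower and 3 higher; HOXA6 had 2 counts against 68 with GSK-J5, 21.2-fold lower (interval 5.65 to 179). Adjusted over the list alone these counts were the same, but for 15 histones lower. Markers of other cell types were lower in these replicates too, in 3 of 3 fibroblast genes (median -4.52, adjusted p = 0.0970), 2 of 2 leukocyte genes (-1.88, adjusted p = 0.356) and 3 of 5 endothelial genes (-2.31, adjusted p = 0.149), the same counts adjusted over the list alone, and these lists did not pass.

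**Figure D2:**
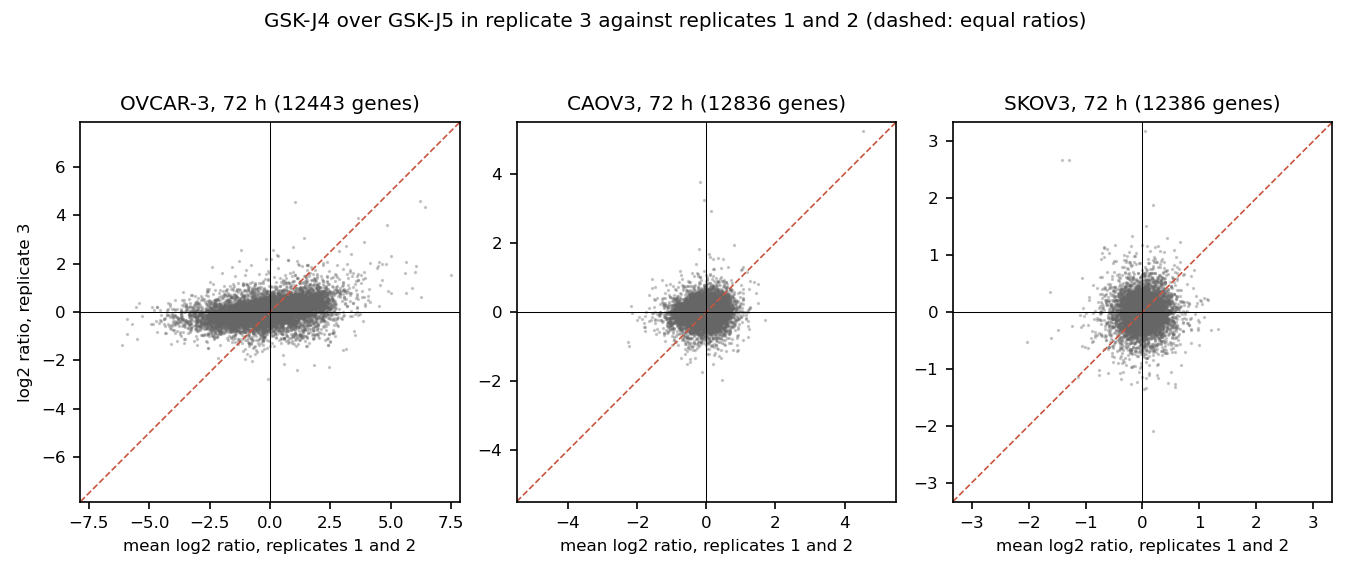
Log2 ratio of GSK-J4 to GSK-J5 in replicate 3 (vertical axis) against the mean of replicates 1 and 2 (horizontal axis) at 72 h, a point per gene, in OVCAR-3, CAOV3 and SKOV3. In OVCAR-3 the slope was 0.116 over 7302 genes, those called in replicates 1 and 2 with an absolute log2 change over 1 there.

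The difference of the effect between 72 h and 48 h in OVCAR-3 was tested as an interaction over all 10 OVCAR-3 libraries. HSPA1A, a heat shock protein 70 gene (ENSG00000204389.9, chromosome 6, 31815464 to 31817946), was 3.70-fold lower with GSK-J4 at 48 h, from 19.6 ± 2.01 to 5.28 ± 0.0414 CPM (n = 2). At 72 h it went from 17.2 ± 1.27 to 26.8 ± 2.29 CPM (n = 3). Its log2 effect differed by 2.56 (interval 2.06 to 3.06, adjusted p = 0.0351), the only gene called by edgeR of 17402, with 1279 at an unadjusted p below 0.05; DESeq2 called 244 genes and voom 0. The heat shock list as a whole was higher at 72 h than at 48 h (13 genes, median difference 0.88, 9 higher adjusted over the list alone, adjusted p = 7.4e-15, and adjusted p = 0.0107 with an estimated correlation). On replicates 1 and 2 alone 11 of the 13 were higher and 0 lower over all genes and adjusted over the list alone (adjusted p = 3.4e-09), and the list did not pass with an estimated correlation (adjusted p = 0.207 with an estimated correlation). The ATF4 list was lower at 72 h than at 48 h, with 7 of 35 genes lower adjusted over the list alone (median difference -1.09, adjusted p = 1.1e-13, adjusted p = 0.689 with an estimated correlation). Its median difference on replicates 1 and 2 alone was -0.54, with 6 higher and 14 lower over all genes and 6 and 18 adjusted over the list alone (adjusted p = 0.0223, adjusted p = 0.395 with an estimated correlation). The median log2 ratio of this list at 72 h was -0.429 in the pair of replicate 3, with 5 of 34 genes above 0, and 28 of 34 were above 0 in each of the other pairs. NRF2 targets had 5 higher and 1 lower adjusted over the list alone (0.53, adjusted p = 0.000248), and mitosis genes a median difference of 0.40 (adjusted p = 1.6e-05), both with an adjusted p = 0.689 with an estimated correlation. The median log2 ratio of the mitosis list was -1.03 and -1.06 in the pairs of 48 h. At 72 h it was -0.84 and -0.818 in replicates 1 and 2 and -0.31 in replicate 3, so its difference rests in part on replicate 3. KDM6B had a difference of -0.70 (adjusted p = 0.499). On replicates 1 and 2 alone 2030 genes had a higher effect at 72 h and 2591 a lower one, with HSPA1A (2.57), HSPA1B (2.12) and CXCL8 (1.96) among the highest and CRB2 (-3.58), TSPEAR-AS2 (-2.88) and GAS1 (-2.50) among the lowest. Across genes, which are not independent replicates, the log2 changes at 72 h and 48 h had a Pearson r of 0.836 and a Spearman rho of 0.857. GSK-J5 at 72 h and 48 h differed in 0 genes by edgeR, with 131 at an unadjusted p below 0.05.

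In CAOV3 at 72 h (n = 3 per compound), changes were small: 11 genes rose and 43 fell of 17137. WFDC21P, a WAP domain pseudogene (ENSG00000261040.7, chromosome 17, 60083566 to 60091885), rose 2.26-fold (log2 1.17, SE 0.224, adjusted p = 0.0386). S100A6, a calcium-binding protein (ENSG00000197956.10, chromosome 1, 153534599 to 153536244), rose 1.41-fold (0.49, SE 0.0863, adjusted p = 0.0358), and NAXE (0.49), an epimerase that repairs hydrated NADH, and the proton pump subunit ATP6V0B (0.47) rose as well. RPLP0P9 (0.51) and RPLP0P6 (0.46) are pseudogenes of a ribosomal protein gene and share sequence with it. GOLGA8A, a golgin of a duplicated family whose reads may not be assigned uniquely (ENSG00000175265.17, chromosome 15, 34379068 to 34437466), was 3.53-fold lower (log2 -1.82, SE 0.360, adjusted p = 0.0403). SAMD9L, an interferon-inducible growth suppressor, was 2.02-fold lower (-1.01, SE 0.197, adjusted p = 0.0403), and the golgin GCC2 (-0.95), the chromatin protein ARID4B (-0.88), ZNF37A (-0.86) and SYNE2 (-0.85), a nuclear envelope spectrin, fell too. KDM6A had a log2 change of -0.25 (interval -0.54 to 0.03, adjusted p = 0.376) and KDM6B one of -0.46 (interval -0.78 to -0.14, adjusted p = 0.134), and on replicates 1 and 2 alone KDM6B fell by 0.63 (adjusted p = 0.0164).

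Among the lists in CAOV3, cholesterol synthesis genes were higher, with 5 of 24 rising adjusted over the list alone and 0 over all genes (median log2 0.19, adjusted p = 6e-06, adjusted p = 0.764 with an estimated correlation). Class I antigen presentation genes (15 measured, 0.19, adjusted p = 0.0289) and the ATF4 list (33 measured, 0.11, adjusted p = 0.0319) were higher with 0 members past the threshold adjusted over the list alone, and both had an adjusted p = 0.565 with an estimated correlation. Mitochondrially encoded protein genes were lower, with 8 of 13 falling adjusted over the list alone and 0 over all genes (-0.25, adjusted p = 0.000225, adjusted p = 0.565 with an estimated correlation). Interferon-stimulated genes had 1 of 32 lower over all genes, OAS3 (-0.48), and 5 adjusted over the list alone (-0.15, adjusted p = 0.00631, adjusted p = 0.764 with an estimated correlation). On replicates 1 and 2 alone 1109 genes rose and 1221 fell of 16554, among them DLGAP1-AS2 (1.73), TMEM256 (1.55), NEB (-2.15), the kinesin CENPE (-1.96), GOLGA4 (-1.87) and AKAP9 (-1.81). In those, 14 cholesterol synthesis genes rose and 0 fell (16 adjusted over the list alone, adjusted p = 2.7e-07, adjusted p = 0.720 with an estimated correlation), among them EBP (0.57) and ACAT2 (0.50). By camera 2 lists passed in these replicates, cholesterol synthesis and the mitochondrially encoded proteins. Class I antigen presentation, the ATF4 list and interferon-stimulated genes did not. The count of 54 fell to 0 without GSK-J5 replicate 1, GSK-J4 replicate 1 or GSK-J4 replicate 2 and to 1 without GSK-J5 replicate 2. It was 2673 and 2639 without GSK-J5 or GSK-J4 replicate 3. A correction for GC content and transcript length, added after the data had been seen, also left 0.

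In SKOV3 at 72 h (n = 3 per compound), 4 genes rose and 3 fell of 16981. HMOX1, which breaks down haem (ENSG00000100292.17, chromosome 22, 35380361 to 35394214), rose 1.52-fold (log2 0.60, SE 0.062, adjusted p = 0.000137), with 47.5, 45.6 and 579 CPM in GSK-J5 replicates 1 to 3 and 73.6, 68.2 and 871 CPM in those of GSK-J4. SCD, the stearoyl-CoA desaturase (ENSG00000099194.6, chromosome 10, 100347124 to 100364834), rose by 0.49 (SE 0.0607, adjusted p = 0.000962). SPP1, which encodes osteopontin, rose by 0.40 (SE 0.0628, adjusted p = 0.0170). ALDH3A1, an aldehyde dehydrogenase (ENSG00000108602.18, chromosome 17, 19737984 to 19748943), was 1.95-fold lower (-0.96, SE 0.0897, adjusted p = 5.5e-05). ESPN, an actin-bundling protein, was 1.86-fold lower (-0.89, SE 0.102, adjusted p = 0.00038), and IDO1, which degrades tryptophan, had a change of -0.59 (SE 0.1, adjusted p = 0.0407). KDM6A and KDM6B both had a log2 change of 0.00, with intervals from -0.19 to 0.19 and from -0.24 to 0.24 (adjusted p = 0.999). With the replicate number as a block 22 genes were called, 6 higher and 16 lower, with all 7 among them. Across genes the difference of replicates 1 and 2 correlated at only 0.0851 between the compounds, so pairing by number beyond the library set has little support.

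By camera 9 of 31 lists passed in SKOV3, with small medians, and 0 with an estimated correlation. All but the cholesterol list had an adjusted p = 0.418 with an estimated correlation. Cholesterol synthesis genes were higher, with 1 of 24 rising over all genes and 4 adjusted over the list alone (median 0.11, adjusted p = 2.7e-06, adjusted p = 0.349 with an estimated correlation). Fatty acid synthesis genes had 1 of 10 higher over all genes and 3 adjusted over the list alone (0.07, adjusted p = 0.000302), and metallothioneins 2 of 4 adjusted over the list alone (0.38, adjusted p = 0.00123). Mitosis genes (0.16, adjusted p = 2e-13) and mitochondrially encoded protein genes (0.11, adjusted p = 2.7e-06) were higher, and DNA replication (-0.12, adjusted p = 0.00523), lineage markers (-0.14, adjusted p = 0.0303) and class I antigen presentation genes (-0.10, adjusted p = 4e-05) were lower. In these 5 lists 0 members passed, over all genes or adjusted over the list alone. Fibroblast markers, measured to detect other cell types, had a median of 0.25 over 10 genes with 1 higher adjusted over the list alone (adjusted p = 0.00128). On replicates 1 and 2 alone, 4 genes rose and 11 fell, among them MEGF6 (-2.0), SHISA2 (-1.61), CYP1B1 (-1.48) and ADGRF1 (-1.30). The count of 7 was 4 without GSK-J5 replicate 2, GSK-J4 replicate 1 or GSK-J4 replicate 2, and 38 without replicate 2.

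**Figure D3:**
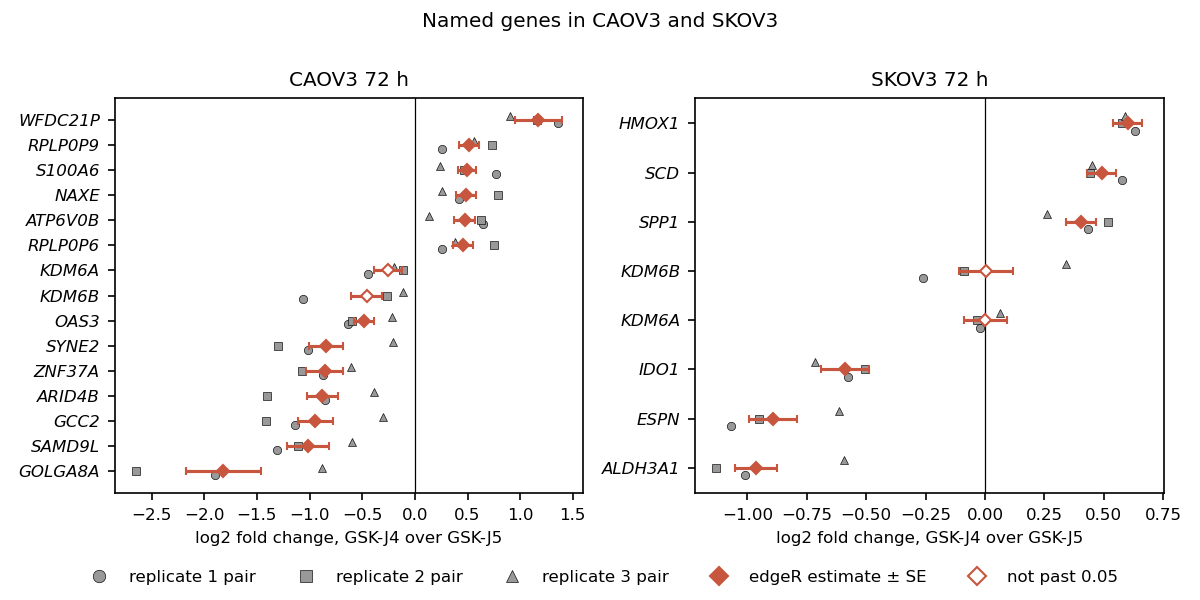
Log2 ratio of GSK-J4 to GSK-J5 of genes named for CAOV3 and SKOV3 at 72 h, with a point for each same-numbered pair and the edgeR estimate with its SE. In SKOV3 the estimates ran from -0.96 for ALDH3A1 to 0.60 for HMOX1, and in CAOV3 from -1.82 for GOLGA8A to 1.17 for WFDC21P.

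The effect of GSK-J4 differed between the 3 lines in 3698 of 20252 genes by the joint edgeR F test, and OVCAR-3 stood apart from the other lines. That fit pools the spread of each gene over the lines. Fitted alone, the common dispersion was 0.109 in OVCAR-3, 0.0361 in CAOV3 and 0.0173 in SKOV3, so pooling understates the spread in OVCAR-3. In the joint fit 7637 genes were called for OVCAR-3 at 72 h, against 5 in its own fit. Compared with CAOV3, OVCAR-3 had a higher effect in 2565 genes and a lower one in 1342. On replicates 1 and 2 alone the balance turned, with 3962 higher and 4257 lower. The differences in NGFR (log2 5.86, SE 0.471, adjusted p = 1.7e-05), MT2A (5.72, SE 0.420, adjusted p = 1e-05) and GDF15 (5.77, SE 1.19, adjusted p = 0.00696) were among the highest. MT2A was at 3106 ± 852 CPM with GSK-J5 in CAOV3 and 3257 ± 932 with GSK-J4 (SD, n = 3), and in OVCAR-3 at 20.9 ± 6.04 and 1493 ± 1050. TTC30A had a lower effect in OVCAR-3 (-3.67, SE 1.04, adjusted p = 0.0260), while the differences called in MT1M, CDH6, LDAH and MECOM rest on counts at or near 0 in a group and are given no size. With GSK-J5, CDH6 and LDAH had 0 counts in all 3 CAOV3 libraries, and MT1M had 1 count in OVCAR-3. Compared with SKOV3, OVCAR-3 had a higher effect in 2637 genes and a lower one in 1585, and on replicates 1 and 2 alone in 3999 and 4329. Among the highest were NGFR (7.72), GDF15 (5.46), MT2A (5.07) and ATF3 (4.68, SE 0.822, adjusted p = 0.00378). The NGFR difference from SKOV3 is larger than its rise of 5.72 in the fit of OVCAR-3 alone. Its size therefore rests in part on the fitted change in SKOV3, where NGFR was not called. The lowest, EPN3, GSAP, METTL7A and AARD, are given no size either, as with GSK-J5 in SKOV3 the first, second and last had 0 counts in all 3 libraries and METTL7A had at most 0.337 CPM. Between CAOV3 and SKOV3 0 genes were called by edgeR, 7 by DESeq2 and 0 by voom, with 1077 at an unadjusted p below 0.05. For KDM6B the effect in OVCAR-3 minus that in CAOV3 was 0.64 (interval 0.14 to 1.15, adjusted p = 0.0698).

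In the lists, OVCAR-3 had a higher effect than CAOV3 in 13 of the 20 aminoacyl-tRNA synthetases (18 adjusted over the list alone, adjusted p = 4.5e-07, adjusted p = 0.382 with an estimated correlation). It had a higher effect in 15 of 18 NRF2 targets with 1 lower (the same counts adjusted over the list alone, adjusted p = 1.5e-08, adjusted p = 0.154 with an estimated correlation). The same held for 12 of 22 NF-kB and cytokine genes with 1 lower (the same counts adjusted over the list alone, adjusted p = 1.4e-06, adjusted p = 0.0568 with an estimated correlation). A lower effect was found in 16 of 30 DNA replication genes (21 adjusted over the list alone, adjusted p = 1.3e-08). It was also found in 11 of 30 mitosis genes (14 lower and 1 higher adjusted over the list alone, adjusted p = 4.6e-07). Both lists had an adjusted p = 0.382 with an estimated correlation. Endoplasmic reticulum chaperones, with 11 of 22 higher and 0 lower (13 adjusted over the list alone), passed with an estimated correlation too (adjusted p = 0.0323 with an estimated correlation). Against SKOV3 the same list (11 higher, and 14 higher and 1 lower adjusted over the list alone, adjusted p = 0.0234 with an estimated correlation) passed both ways. NF-kB and cytokine genes did so as well (10 higher and 1 lower, and 11 and 1 adjusted over the list alone, adjusted p = 0.0234 with an estimated correlation). Mitosis had 16 of 30 lower (23 lower and 1 higher adjusted over the list alone, adjusted p = 3.1e-10, adjusted p = 0.362 with an estimated correlation). Between CAOV3 and SKOV3 class I antigen presentation (median difference 0.32, 0 called and 1 higher adjusted over the list alone, adjusted p = 0.000293, adjusted p = 0.187 with an estimated correlation) passed. So did mitosis (-0.18, 0 called and 1 lower adjusted over the list alone, adjusted p = 0.0016, adjusted p = 0.996 with an estimated correlation). The F test count was 0 without replicate 1 or 2 and 8857 without replicate 3. With DESeq2 size factors 55.4% of the genes that differed between OVCAR-3 and CAOV3 were higher in OVCAR-3, against 65.7% with TMM.

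**Figure D4:**
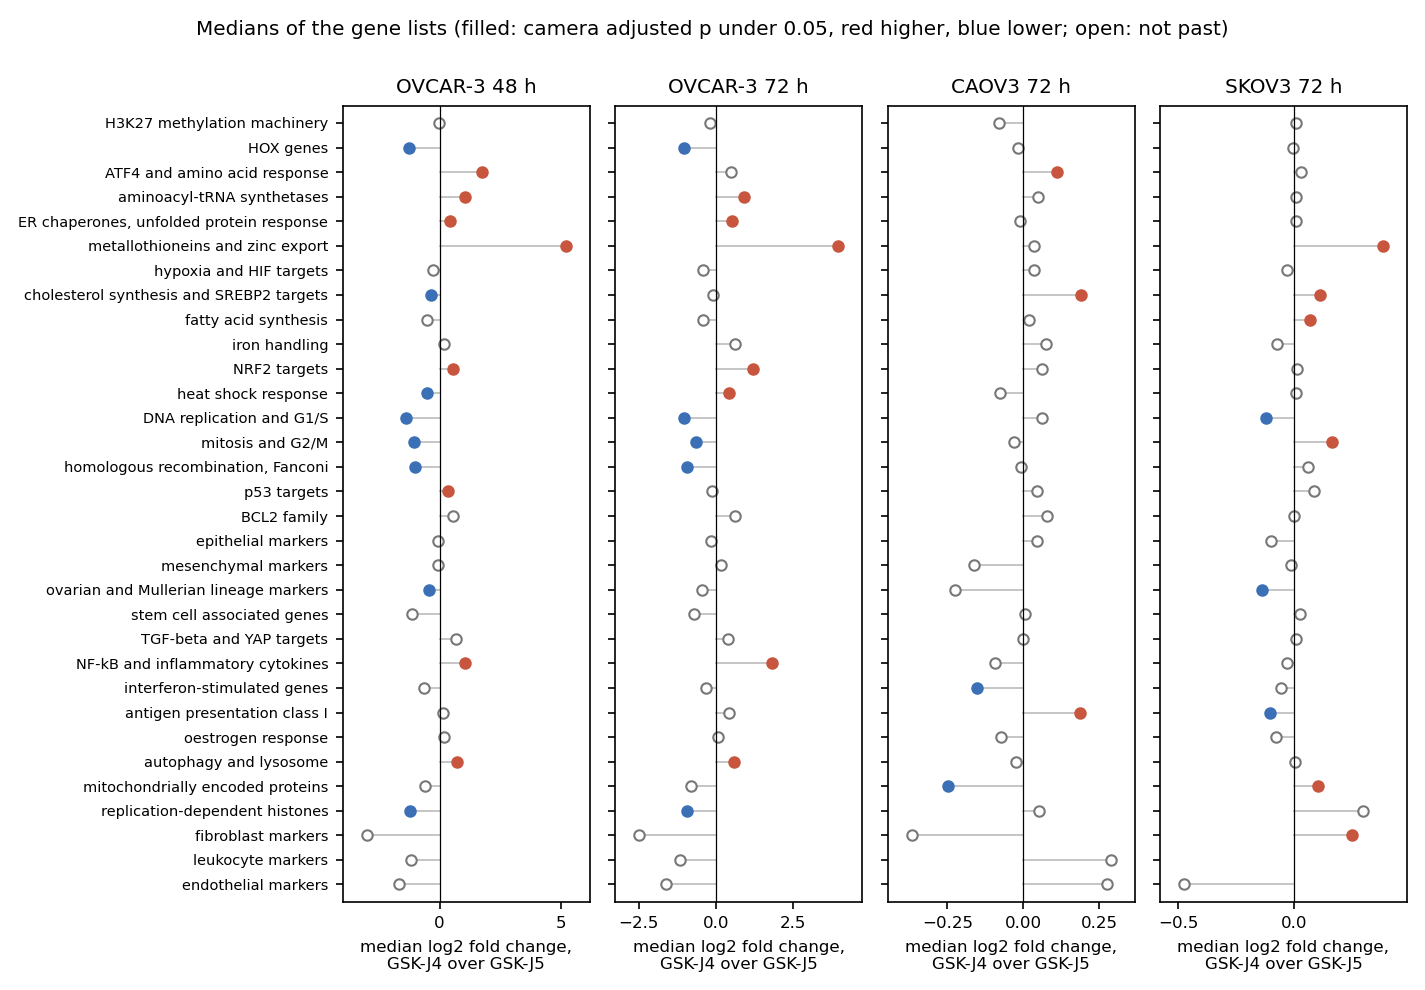
Median log2 fold change of GSK-J4 against GSK-J5 over the measured members of each of the 32 gene lists (horizontal axis), in OVCAR-3 at 48 h and 72 h, CAOV3 and SKOV3, with filled points for lists with a camera adjusted p under 0.05. The metallothionein list has the highest medians, 5.19 at 48 h and 3.97 at 72 h in OVCAR-3.

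No gene was called in the same direction in all 3 lines at 72 h: 0 by edgeR, DESeq2 and voom, of 14272 tested in each by edgeR. With so few calls independent lists would give 3.93e-07 higher genes and 0 lower ones. At an unadjusted p below 0.05 in every line, 16 genes were higher and 8 lower, where independent lists would give 4.73 and 5.76. Among them, named after their values were seen, were DUSP5, a phosphatase that acts on ERK (log2 1.53 in OVCAR-3, 0.50 in CAOV3, 0.36 in SKOV3), DHCR7, the last enzyme of cholesterol synthesis (0.55, 0.31, 0.30), IL18 (2.64, 0.26, 0.49) and the uridine phosphorylase UPP1 (3.61, 0.46, 0.23). On the lower side were SAMD9 (-2.92, -0.78, -0.30), the cadherin FAT2 (-1.40, -0.73, -0.49), the laminin chain LAMB2 (-1.45, -0.28, -0.23) and the semaphorin receptor NRP2 (-1.53, -0.68, -0.22). On replicates 1 and 2 alone OVCAR-3 and CAOV3 shared 683 higher genes (399 from independent lists) and 606 lower ones (425). In both lines the log2 ratios of these replicates ran with the log of transcript length. The correlations across genes were -0.21 and -0.138 in OVCAR-3 and -0.206 and -0.254 in CAOV3, and no overlap was computed after a length correction. In these replicates all 3 lines shared 0 called genes, where independent lists would give 0.0867 higher and 0.308 lower. OVCAR-3 and SKOV3 shared HMOX1 on the higher side (1.11 genes from independent lists) and 8 genes on the lower side (3.64 from independent lists), among them CYP1B1, ALDH3A1, ESPN and MEGF6. Across genes, which are not independent replicates, the log2 changes at 72 h had a Pearson r of 0.133 and a Spearman rho of 0.198 between OVCAR-3 and CAOV3, and 0.0169 and 0.0518 between OVCAR-3 and SKOV3. They were -0.0123 and -0.00678 between CAOV3 and SKOV3. Intervals of the effect lay within a log2 value of 1 on both sides of 0 for 69.1% of genes in CAOV3 and 73% in SKOV3, and for 28.3% in OVCAR-3.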

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

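The tests on the replicate 3 libraries of OVCAR-3, the one on the ATF4 list, the list test without replicate 3 and the corrections for GC content and length were chosen only after the result was seen. Intervals in this part come from 1000 draws of genes with replacement (bootstrap). Genes are not independent replicates, so these intervals do not cover the spread between libraries. What is said of OVCAR-3 replicate 3 rests on a single pair of libraries.

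The difference between lines stood out by its own tests, in a fit that pools the spread of the lines. In it 3698 genes differed in their effect over the 3 lines, 3907 between OVCAR-3 and CAOV3 and 4222 between OVCAR-3 and SKOV3. Over 21 groupings of the libraries, the real one included, the F test gave 3698 genes in the real one and at most 3149 in another, so that 1 of 21 was as high (4.76%, the smallest share possible). For OVCAR-3 against SKOV3 the values were 4222 and at most 3928, again 1 of 21. For OVCAR-3 against CAOV3 they were 3907 and 4042, so that 2 of 21 were as high (9.52%) and chance cannot be excluded, and for CAOV3 against SKOV3 0 and 2, with 21 of 21. In the F test 4 of the 20 other groupings gave over 1000 genes (2366 to 3149), and in all 4 the grouping of the OVCAR-3 libraries was the real one. The other 2 groupings that kept OVCAR-3 replicates 1 and 2 parted by treatment as in the real one, but not replicate 3, gave 7 and 0, and the highest count among the rest was 1. This points to a structure of the samples: in these groupings high counts came only with all OVCAR-3 libraries in their real groups. The real grouping therefore stands against only 4 comparable ones, too few for a share under 0.05, and chance is not taken as excluded for any of these counts. Without replicate 1 or without replicate 2, 0 genes were called in the F test and for OVCAR-3 against SKOV3, and with the replicate block these counts were 668 and 1294.

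Within a line the 10 splits of 3 against 3 cannot give a share under 0.1. The splits do not keep the same-numbered pairs, and some put both replicate 3 libraries in the same group, unlike the real grouping. The highest other values of 14 lists in OVCAR-3 and 4 genes in SKOV3 came from such splits, so they are not fully comparable with the real one. A comparable split of OVCAR-3, with GSK-J5 replicate 3 beside GSK-J4 replicates 1 and 2, gave 13 lists and 0 genes. That split exchanges the labels of the replicate 3 pair, and its list count was also above the real one. The real value and the highest other were 5 and 0 genes in OVCAR-3, 54 and 1 in CAOV3, and 7 and 4 in SKOV3, with 1 of 10 splits as high in each. For the lists they were 12 and 14 in OVCAR-3, with 4 of 10 as high, 5 and 3 in CAOV3 and 9 and 8 in SKOV3, with 1 of 10 as high in both.

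The first pattern is the smaller response of OVCAR-3 replicate 3, where the log2 ratio had a slope of 0.116 (interval 0.105 to 0.127) on the effect of replicates 1 and 2 over 7302 genes, picked as called in those replicates with an absolute log2 change over 1, and 69.9% of genes had the same sign. That positive slope argues against exchanged labels in this pair. Over these 7302 genes as a set, GSK-J5 replicate 3 lying near the treated state is argued against as well. GSK-J4 replicate 3 reached a slope of only 0.243 (0.234 to 0.253) from the GSK-J5 libraries of replicates 1 and 2, where GSK-J5 replicate 3 itself stood at 0.133. A mixture of treated and untreated RNA in GSK-J4 replicate 3 stays open: the share of the CPM rise of replicates 1 and 2 that it reached, over 82 genes, had a quartile ratio of 2.89 (1.87 to 5.35), with 0.681 for NGFR and 0.134 for MT2A. The library set is replicate 3 itself, so a difference in medium, kit or culture cannot be told apart from it, and no biological explanation was tested.

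For the ATF4 list, with a median log2 ratio of -0.429 in the replicate 3 pair, GSK-J4 replicate 3 stood at 63.6% (36.9 to 97.9) of the effect when measured from the GSK-J5 libraries of replicates 1 and 2. GSK-J5 replicate 3 was above those libraries by a median of 1.37, with 33 of 34 genes above 0. The median effect of GSK-J4 on this list in replicates 1 and 2 was 1.06, so for this list GSK-J5 replicate 3 lay above that level.

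The second pattern is the fall of 43 genes in CAOV3, whose transcripts were long and low in GC. Their median transcript length was 7594 bases against 3222 for the genes tested, and their GC content 38.7% against 48.8%. The 11 that rose had a median transcript length of 673 bases and a GC content of 54.2%. After a correction for GC content and length the median log2 change went from -0.66 to -0.49, so 74.9% (69.9 to 82.7) was left. The median of the SEs of the single genes went from 0.128 to 0.117, and 0 of 43 genes passed. With a correction for length alone 71.9% (68.0 to 80.4) was left, with a median of -0.47 and 0 past the threshold. The 43 genes were picked by the uncorrected fit of these same libraries, so a part of their change would be left under either explanation. The share left therefore cannot decide whether the trend is the source of the fall. The same-numbered pairs had medians of -0.82, -0.91 and -0.26, and an effect of GSK-J4 on genes with long transcripts stays open and untested.

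The third pattern is the heat shock genes in OVCAR-3, with HSPA1A as the 1 gene whose effect differed between 72 h and 48 h (log2 difference 2.56) and the whole list past its test (adjusted p = 7.4e-15). With voom, or with the replicate block in place of the set term, 0 genes were called for this difference. A drift of the GSK-J5 libraries between the times is argued against, since the median change in GSK-J5 was -2.22% (-16.1 to 6.64) of the median difference. Reads shared by HSPA1A and HSPA1B are argued against only for the rest of the list, the other 11 members. Without HSPA1A and HSPA1B 90.3% (75.5 to 138) of the median difference was left (camera p = 1.9e-11, p = 0.00089 with an estimated correlation, fry p = 3.1e-05). For the call of HSPA1A itself this test cannot decide, since it leaves that gene out. Without replicate 3 the list passed with the preset correlation (adjusted p = 3.4e-09) and not with an estimated one (adjusted p = 0.207 with an estimated correlation). A time-dependent heat shock response to GSK-J4 stays open and was not tested, and the pattern rests on 2 libraries per compound at 48 h.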

How the results depend on the processing

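The corrections for GC content and transcript length, the list tests without replicate 3 and the named-gene rule on replicates 1 and 2 were chosen only after the result was seen. The OVCAR-3 72 h count of 5 was 7618 in the fit of 10 libraries, 1326 with no low-count filter, 6334 with the DESeq2 Wald test. It was 1 with no set term, 0 with the replicate block, 7637 with a spread shared over the lines, and 0 to 11823 with replicates or single libraries left out. The CAOV3 count of 54 was 832, 668 and 505 with no filter, DESeq2 and voom (54, 50 and 54 of the genes shared). It was 0 with no set term, the block or a shared spread, 3 with a log2 threshold of 1, 0 with correction for GC content and length, for length and for GC content, and 0 to 2673 with libraries left out. The SKOV3 count of 7 was 31, 19 and 11 with no filter, DESeq2 and voom, 0 with no set term, a shared spread or a log2 threshold of 1, 22 with the block, and 4 to 38 with libraries left out. The OVCAR-3 48 h count of 3296 was 5864 with DESeq2, 811 with no set term, 606 with the block, 10206 from the 48 h libraries alone, and 0 to 10076 with libraries left out. The time difference, 1 gene, was 20 with no filter, 244 with DESeq2, 0 with voom and the block, and 0 to 4621 with libraries left out. The F test of the lines, 3698, was 5933 with DESeq2, 576 with no set term, 668 with the block and 0 to 8857 with libraries left out. OVCAR-3 against CAOV3, 3907, was 671 with no set term, 1336 with the block, 2419 with a log2 threshold of 1 and 0 to 8219 with libraries left out, and OVCAR-3 against SKOV3, 4222, was 795, 1294, 2601 and 0 to 8328. CAOV3 against SKOV3, 0 by edgeR with 1077 at an unadjusted p below 0.05, was 87 with no filter, 7 with DESeq2, 0 with voom and 0 to 448 with libraries left out. Genes called in all 3 lines were 0 in edgeR, DESeq2 and voom and under every alternative run, with 16 higher and 8 lower at an unadjusted p below 0.05. The lists called fell from 12 to 0 with an estimated correlation and 4 with fry in OVCAR-3 at 72 h, from 5 to 0 and 0 in CAOV3 (2 without replicate 3), and from 9 to 0 and 0 in SKOV3. They fell from 9 to 1 and 2 for the time difference and from 2 to 0 and 0 for CAOV3 against SKOV3. With an estimated correlation they fell from 16 to 0 in OVCAR-3 at 48 h and from 12 to 1 and 13 to 2 for OVCAR-3 against CAOV3 and SKOV3, while fry called 18, 11 and 13.

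Reversed directions were those of genes near 0 or with few counts. For OVCAR-3 72 h, KDM6A log2 fold change (-0.01) was 0.0206 in the fit of 10 libraries, 0.0459 with DESeq2 size factors, 0.0464 with the Wald test, 0.00684 with a shared spread and -0.109 to 0.102 with libraries left out. For OVCAR-3 72 h, HOXD11 log2 fold change was -3.37 to 1.40 with libraries left out. KDM6A in SKOV3 was -0.00446 with voom, -0.00179 with no set term and -0.0283 to 0.0181 with libraries left out, and KDM6B -0.168 to 0.129. LINC01127 in OVCAR-3 against CAOV3, a fitted value on counts near 0, was -9.19 without replicate 3 and 0.52 without replicate 1. Of the values of named genes over the alternatives, 286 of 480 kept direction and side of the threshold in CAOV3, 161 of 224 in SKOV3, 409 of 646 in OVCAR-3 at 72 h and 300 of 574 at 48 h. The repeats that leave libraries out have fewer libraries by construction, and for the other alternatives the cause was not tested. Alternatives fixed for normalized values were not run, since the values are counts. At a true log2 change of 1 the simulated fits recovered 7% of changed genes in OVCAR-3 at 72 h and 17% at 48 h, against 79% in CAOV3 and 100% in SKOV3. These simulations gave every gene the same dispersion and every replicate the same change, unlike the real OVCAR-3 libraries of 72 h.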

Other observations

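The genes named in this part were chosen after their values were seen, and the repeats without replicate 3 were chosen only after the result was seen.

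The mitochondrial ribosomal RNA gene MT-RNR2 rose with GSK-J4 in OVCAR-3 at 48 h (log2 2.60, SE 0.547, adjusted p = 0.0257). At 72 h MT-RNR2 had a log2 change of 3.19 (SE 0.548, adjusted p = 0.0700) with 3 replicates, and it rose on replicates 1 and 2 alone (3.93, SE 0.197, adjusted p = 2.3e-06). In CAOV3 and SKOV3 MT-RNR2 had changes of 0.10 (adjusted p = 0.60) and 0.02 (adjusted p = 0.999). The protein gene MT-CYB of the same genome had a change of -0.61 (adjusted p = 0.231) in OVCAR-3 at 48 h. The list of mitochondrially encoded proteins had a median of -0.61 there (2 of its members lower, adjusted p = 0.304) and of -0.82 at 72 h (adjusted p = 0.119). That list was fixed as a check of library type, and whether library make-up moved MT-RNR2 was not tested. CYP1A1 and CYP1B1, cytochrome P450 genes induced through the aryl hydrocarbon receptor, fell at 48 h in OVCAR-3, CYP1A1 by a log2 change of -3.20 (SE 0.417, adjusted p = 0.0118) and CYP1B1 of -2.87 (SE 0.50, adjusted p = 0.0185). In SKOV3 CYP1B1 had a change of -1.10 (SE 0.305, adjusted p = 0.999) and fell on replicates 1 and 2 alone (-1.48, SE 0.0820, adjusted p = 2.4e-08), and in CAOV3 it had a change of -0.16 (adjusted p = 0.758).

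Several lists that did not pass in OVCAR-3 at 48 h held called genes. In the H3K27 methylation machinery 4 rose and 3 fell of 24 (4 and 6 adjusted over the list alone, median log2 -0.05, adjusted p = 0.95). In the hypoxia list 4 rose and 7 fell (-0.26, adjusted p = 0.160), and in the TGF-beta and YAP list 8 and 2 (0.66, adjusted p = 0.126). The BCL2 family had 6 higher and 1 lower (0.53, adjusted p = 0.115), the oestrogen response list 6 and 0 (0.16, adjusted p = 0.221), and interferon-stimulated genes 1 and 4 (-0.62, adjusted p = 0.0601). Epithelial markers had 2 higher and 4 lower (-0.06, adjusted p = 0.447), mesenchymal markers 0 and 0 (-0.06, adjusted p = 0.95), and stem cell associated genes 4 and 3 (-1.12, adjusted p = 0.437). Markers of other cell types did not pass: fibroblast -2.99 (adjusted p = 0.115), leukocyte -1.17 (adjusted p = 0.419) and endothelial -1.67 (adjusted p = 0.155).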
